A study of Mus musculus with 14 samples.

How the data were processed

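Gene expression was measured on 14 mouse Affymetrix MOE430 2.0 arrays, 1 array per RNA sample. The cells were p14 cells, CD8 T cells with a transgenic receptor for a peptide of lymphocytic choriomeningitis virus (LCMV), which carried the congenic marker CD90.1 and had been transferred into B6 mice. Spleens of individual chimeric mice infected with the Armstrong strain were taken 8 days (effector cells) or 46 days (memory cells) after infection, and the p14 cells were enriched magnetically and sorted. Each mouse's sorted cells were split, so that RNA was taken from an ex vivo aliquot and from an aliquot stimulated for 3 h with plate-bound anti-CD3 (10 ug/ml) and soluble anti-CD28 (2 ug/ml). The groups held 3 effector ex vivo, 3 effector stimulated, 4 memory ex vivo and 4 memory stimulated arrays. Per the labels, infections were staggered so that effector and memory cells were collected at the same time, RNA was amplified and biotin-labelled with a NuGEN Ovation kit, and the ex vivo arrays were re-analysed from earlier work, whereas the titles of the stimulated arrays do not say so. Any array batch that followed this difference cannot be told apart from stimulation. There were no cells cultured for 3 h without stimulation, so for every gene effects of the culture cannot be told apart from those of stimulation.

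The deposited values are log2 signals that the authors made with RMA, which corrects the background, normalizes arrays by quantiles and summarises each probe set. The RMA version and software were not stated. No raw images were processed here. The table held 45101 probe sets. Of these, 34945 carried exactly 1 gene symbol in the array annotation, 932 carried several, and 9211 were unnamed, 51 Affymetrix controls included. The other 13 controls carried a symbol and were not used as genes. The Entrez identifiers of 34741 of the 34945 probe sets matched the mouse gene reference. Each of the 18193 gene symbols was represented by its probe set of highest mean over the 14 arrays, and a gene was tested when this probe set lay above the 30th percentile of its array on at least 3 arrays, which left 15487 genes. An array gives no count of molecules, so the number of arrays limits the precision. Signals near 3 on the log2 scale lie at the background, where fold differences are compressed.

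Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, statmod 1.5.0), in a model with a mean for each of the 4 groups and a residual spread shared by them. The 5 comparisons were stimulated minus ex vivo cells at each day, memory minus effector cells ex vivo and after stimulation, and the interaction, which is the response of memory cells minus that of effector cells. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. Values are log2 differences with the standard error (SE) of the model, or group means with the standard deviation (SD). The comparisons, the rule for named genes, the 30 gene lists and most alternatives were fixed before the data were examined.

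The lists covered chemokines, chemokine receptors, cytokines, cytotoxic effector molecules, killer cell lectin-like and NK receptors, inhibitory receptors, costimulatory and activation receptors, immediate early and activation transcription factors, NF-kB pathway genes, negative regulators of T cell signalling, memory and naive associated genes, effector differentiation genes, cell cycle S phase, cell cycle G2 and M phase, glycolysis, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, cholesterol synthesis, type I interferon stimulated genes, the integrated stress response with amino acid uptake, and heat shock genes. Another 8 lists held markers of B cells, macrophages with monocytes and dendritic cells, neutrophils, erythroid cells, CD4 T cells, NK cells, platelets, and stroma with endothelium. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison, then with camera and an estimated correlation, and with fry, which tests whether a list's genes moved on balance in a common direction and compares them with no other genes. A list's count of genes past the threshold is given over all genes tested and adjusted over the list alone. In 23 of 150 list results the median, the mean and camera differed in sign, and 0 of these were called by camera.

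Named genes came from a rule: per comparison the 10 largest positive and 10 largest negative differences past the threshold with all arrays of the groups separate (the interaction without this condition), up to 4 members of each list with the largest difference, and any chemokine. The text names a selection of the genes this rule gave, made after their values were seen. Ifng lies outside the rule and was chosen after its values were seen. Where another probe set of a gene named as changed passed with the opposite sign, the gene was left out of the text.

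The labels number the replicates of each group but do not state that a number marks the mouse. Residuals of same-numbered ex vivo and stimulated arrays had correlations across genes of 0.04, 0.09 and 0.07 for effector cells and 0.10, -0.15, -0.05 and -0.22 for memory cells, and limma's consensus correlation was -0.022. Because aliquots came from the same sorted samples, a fit with same-numbered arrays of a day as a fixed block (paired by mouse) is given beside the comparisons of stimulated with ex vivo cells and the interaction. This reading of the numbers was adopted after the counts of the blocked fits had been seen.

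Other settings were median, quantile and cyclic loess scaling between arrays, no filter or a stricter filter (50th percentile), eBayes with trend and robust options, array weights, a fit of the 2 groups compared alone, the mean of a gene's probe sets, every probe set tested on its own, x_at and s_at probe sets left out, a 2-fold minimum, a threshold of 0.01, blocks by replicate number, genes held by another list left out of a list, and each array left out in turn. A pair of alternatives was chosen after seeing the data: memory stimulated replicates 2 and 3 left out together, and the difference between the 3' and 5' beta-actin control signals of each array as a covariate. This actin difference was at least 1.26 on each memory stimulated array and at most 1.10 on every other array. The covariate thus overlaps with that group and can widen the SEs of its comparisons. A call lost with it does not separate RNA length from the group difference. The pipeline was tested on simulated data with 15487 genes, in which it recovered 67.2% (effector response), 71.6% (memory response), 70.1% (memory minus effector ex vivo), 64.2% (memory minus effector after stimulation) and 35.8% (interaction) of genes changed by 1 log2 unit. In the simulation, noise was drawn independently for each gene, with the gene's own spread and a factor for each array. There, 74 of 278 calls for the memory response and 42 of 204 calls after stimulation were of unchanged genes. Such calls were 0 of 151, 1 of 168 and 2 of 87 in the effector response, the ex vivo comparison and the interaction. Deviations shared by many genes were not simulated and few genes were changed, so these shares need not hold for the data.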

Results

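The data were RNA signals of virus-specific CD8 T cells (p14 cells) from the spleens of mice infected with LCMV, taken at the effector stage (day 8) or the memory stage (day 46), either directly ex vivo or after 3 h of stimulation through CD3 and CD28. The groups held 3 effector ex vivo, 3 effector stimulated, 4 memory ex vivo and 4 memory stimulated arrays, and 15487 genes were tested. Transcripts of the sorted cells were abundant on the log2 scale. Cd8a had mean signals of 11.7, 11.7, 11.7 and 11.1 and Cd3e of 11.9, 11.6, 11.8 and 11.5 in effector ex vivo, effector stimulated, memory ex vivo and memory stimulated cells. Cd3d had means of 11.9, 11.7, 11.9 and 11.2 and Thy1, the gene of CD90, of 10.2, 9.60, 9.83 and 8.98. Upon stimulation Cd8b1 differed by -1.03 in effector and -1.92 in memory cells, to means of 10.1 and 9.07. Cd3g differed by -0.58 and -1.08, Cd3d by -0.27 and -0.76 and Thy1 by -0.62 and -0.85. These differences passed in limma. Cd3e (-0.30) and the probe set that represents Cd8a (-0.62) passed in memory cells only. The interaction was -0.58 for Cd8a (adjusted p = 0.036) and -0.88 for Cd8b1 (adjusted p = 0.033). It did not pass for Cd3e, Cd3d, Cd3g and Thy1.

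Array quality differed between groups. The interquartile range of all probe sets was 2.11 and 2.58 log2 units on memory stimulated replicates 2 and 3 and 3.18 to 3.40 on the other 12 arrays. Mean Pearson correlations with the other arrays of a group, across probe sets that are not independent replicates, were 0.919 to 0.966 in memory stimulated cells and at least 0.993 in the other groups. The median SD of a gene was 0.125, 0.133, 0.146 and 0.380 in effector ex vivo, effector stimulated, memory ex vivo and memory stimulated cells. The signal of beta-actin control probe sets at the 3' end minus that at the 5' end, a measure of RNA length, was 0.77, 1.00, 0.88 and 1.48 log2 units in the same order.

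**Figure D1:**
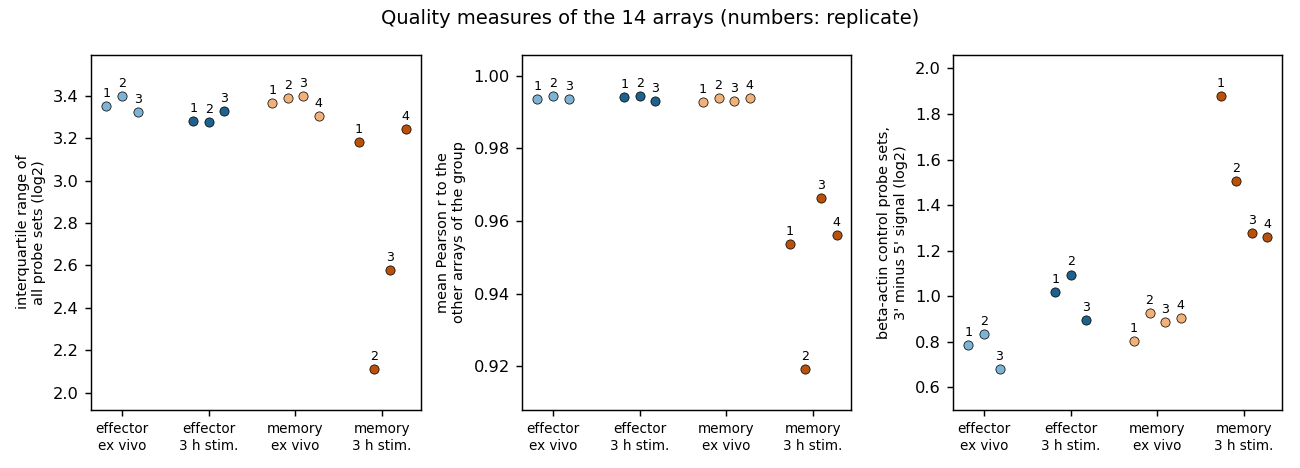
Quality of each array by group, with replicate numbers at the points: interquartile range of all probe sets (log2), mean Pearson correlation with the other arrays of the group, and 3' minus 5' signal of the beta-actin controls (log2). Memory stimulated replicates 2 and 3 have the lowest interquartile ranges, 2.11 and 2.58, and replicate 2 has the lowest correlation, 0.919.

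Stimulated and ex vivo effector cells were compared to ask which transcripts effector cells change within 3 h of receptor and costimulatory engagement. Changes due to the culture itself are part of this difference. Single cytokine and chemokine genes had the largest rises. Il2, the T cell growth factor, rose by 9.32 log2 units (SE 0.18, n = 3 and 3, adjusted p = 2.6e-12) and Csf2 by 8.84 (SE 0.33). The rise was 9.14 (SE 0.17) for Ccl1, a ligand of Ccr8, and 8.44 (SE 0.16) for Xcl1, which attracts cross-presenting dendritic cells. Among 28 chemokines 8 rose and 2 fell (8 and 2 adjusted over the list alone). Ccl4 rose by 4.29 (SE 0.15), Ccl9 by 3.53 (SE 0.18) and Ccl3 by 3.40 (SE 0.21). The difference was -0.44 (SE 0.11, adjusted p = 0.0073) for Ccl5 and -1.95 (SE 0.23) for Ccl6. Camera called the chemokine list higher (adjusted p = 0.0025), with adjusted p = 0.25 with an estimated correlation. Of 30 cytokines 20 rose and 3 fell (21 and 3 adjusted over the list alone), among them Il21 (6.74), Tnf (6.54) and Il3 (6.36). The cytokine list had a camera adjusted p of 4.7e-14, and adjusted p = 0.0038 with an estimated correlation. Ifng, chosen after its values were seen, was already at a mean signal of 11.3 ex vivo and rose by 1.64 (SE 0.11). Its stimulated signal thus lay near the upper end of the arrays, where differences can be compressed.

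**Figure D2:**
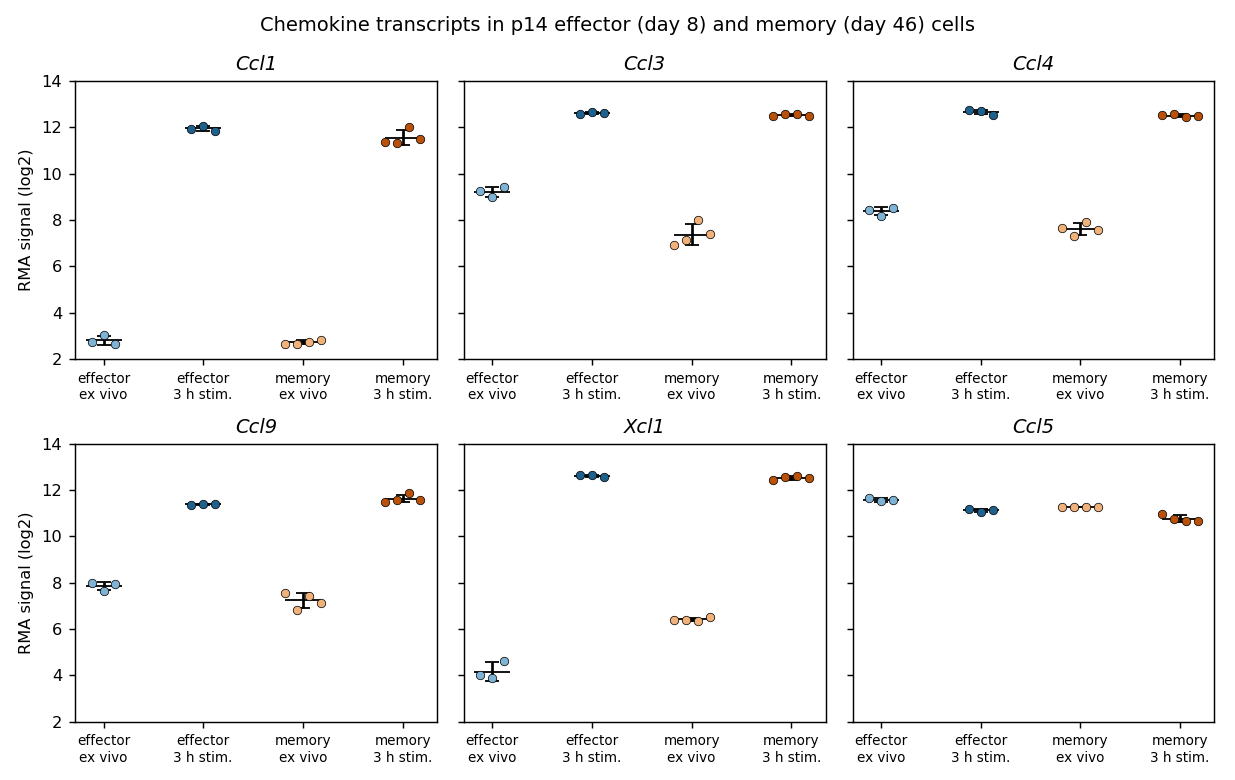
RMA signal (log2) of 6 chemokine genes in each array (points) by group, with the group mean (dash) and SD (bar). Xcl1 rises from a mean of 4.17 in effector and 6.42 in memory cells ex vivo to 12.6 and 12.5 after stimulation, while Ccl5 lies between 10.8 and 11.6 in the group means.

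Activation receptors and transcription factors also rose in effector cells. Of 18 costimulatory and activation receptors 11 rose and 1 fell (11 and 2 adjusted over the list alone), with Il2ra, a chain of the IL-2 receptor, up by 4.76 and Tnfrsf9 (4-1BB) by 4.61. Among 12 inhibitory receptors 7 rose and 1 fell (7 and 1 adjusted over the list alone), including Pdcd1 (PD-1, 3.49) and Havcr2 (TIM-3, 3.26). Of 31 immediate early and activation transcription factors 21 rose and 2 fell (23 and 2 adjusted over the list alone), led by Atf3 (5.77), Egr3 (5.52) and Egr2 (5.48). Of 20 NF-kB pathway genes 16 rose and 1 fell (16 and 2 adjusted over the list alone), including Nfkbid (5.36) and Rel (4.06). All 32 ribosome biogenesis genes rose (32 adjusted over the list alone), such as Nop16 (4.16) and Nop2 (3.27). The integrated stress response and amino acid uptake list had 16 of 18 genes higher (16 adjusted over the list alone), such as Asns, asparagine synthetase (4.88), and the transporter Slc7a5 (3.98). Camera called these 6 lists higher, with adjusted p from 2.9e-34 to 1.1e-04, and held each call with an estimated correlation (adjusted p from 0.0038 to 0.018). Of 32 negative regulators of T cell signalling 17 rose and 8 fell (19 and 9 adjusted over the list alone), with Cish up by 4.65 and Spry1 by 4.25 (camera adjusted p = 7.1e-06, adjusted p = 0.064 with an estimated correlation).

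Interferon stimulated and cell cycle genes fell in stimulated effector cells. Of 25 type I interferon stimulated genes 19 fell and 1 rose (21 and 1 adjusted over the list alone) (camera adjusted p = 4.4e-10, adjusted p = 0.029 with an estimated correlation). The difference was -3.92 (SE 0.33) for Mx1, -3.69 for Oas3 and -3.25 for Rsad2, which encode antiviral proteins. In cell cycle G2 and M phase 26 of 34 genes fell (29 adjusted over the list alone; camera adjusted p = 1.4e-09, adjusted p = 0.25 with an estimated correlation), such as Racgap1 (-3.36) and Ccnb2 (-2.46). In cell cycle S phase 13 of 31 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 5.7e-05, adjusted p = 0.22 with an estimated correlation), with Tk1, thymidine kinase, at -2.65. The largest fall was that of S1pr5 (-5.47, SE 0.27), a sphingosine 1-phosphate receptor, and S1pr1 (-3.45) and its activator Klf2 (-3.50) fell too. The lists that hold these genes were not called by camera. In them 7 of 20 effector differentiation genes fell and 3 rose (7 and 4 adjusted over the list alone; camera adjusted p = 0.62), and 9 of 22 memory and naive associated genes fell and 3 rose (9 and 4 adjusted over the list alone; camera adjusted p = 0.19). Cytotoxic effector molecules went both ways, with 6 of 19 higher and 5 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.72), Fasl at 2.51 and Tnfsf10 (TRAIL) at -2.57. Of 14 killer cell lectin-like and NK receptors 6 fell (6 adjusted over the list alone; camera adjusted p = 0.065, fry adjusted p = 4.0e-04). Camera called this list without effector ex vivo replicate 2 (adjusted p = 0.043), effector stimulated replicate 1 (0.037), memory ex vivo replicate 2 (0.034) or memory stimulated replicate 3 (0.049).

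In all, 4229 genes passed the threshold between stimulated and ex vivo effector cells, 1628 higher and 2601 lower, and 2381 of them differed at least 2-fold. In 4211 of them every array of one group lay above every array of the other, as for each gene named here as changed in this comparison. Such separation held for 7887 of all 15487 genes tested, where chance alone would give 10.0%. Among markers of other cells, 2 of 14 B cell genes fell, 3 of 15 macrophage, monocyte and dendritic cell genes fell, 1 of 5 erythroid genes rose, and 2 of 4 NK cell, 1 of 7 platelet and 1 of 9 stromal and endothelial genes fell. None of 7 neutrophil markers passed in limma (0 at an unadjusted p under 0.05, fry adjusted p = 0.78). Of 9 CD4 T cell markers 3 rose, Tnfrsf4 (3.93), Cd40lg (2.87) and Icos (1.60), which activated CD8 T cells express as well and other lists hold too (camera adjusted p = 0.019, adjusted p = 0.064 with an estimated correlation). Without the genes that other lists hold too, the call was lost (adjusted p = 0.75, from 2.5e-07 to 0.75 over 30 settings). Paired by mouse in a fixed block, 3728 genes passed. Without memory stimulated replicates 2 and 3, whose spread enters the shared variance, 6396 genes passed, among them all 4229, an alternative chosen after seeing the data.

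The same comparison in memory cells asked which transcripts early memory cells change upon stimulation. Il2 rose by 9.23 log2 units (SE 0.16, n = 4 and 4, adjusted p = 3.4e-13), Ccl1 by 8.83 (SE 0.15) and Csf2 by 8.12 (SE 0.28). Bcat1, a branched-chain aminotransferase, rose by 8.62 (SE 0.17) and Tnfsf11, which encodes the cytokine RANKL, by 7.80 (SE 0.19). Of 28 chemokines 11 rose and 2 fell (11 and 2 adjusted over the list alone). Xcl1 rose by 6.11 (SE 0.14), Ccl3 by 5.16 (SE 0.18), Ccl4 by 4.90 (SE 0.13) and Ccl9 by 4.39 (SE 0.16). The difference was -0.50 (SE 0.09) for Ccl5 and -1.52 (SE 0.20) for Ccl6. The chemokine list was called higher by camera (adjusted p = 2.8e-04, adjusted p = 0.19 with an estimated correlation), and 7 rather than 11 chemokines rose without memory stimulated replicates 2 and 3. Ifng rose by 1.85 (SE 0.09), with the same limit near the upper end of the arrays as in effector cells.

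In memory cells 19 of 30 cytokines rose and 4 fell (20 and 4 adjusted over the list alone; camera adjusted p = 2.0e-06, adjusted p = 0.025 with an estimated correlation). Of 31 immediate early and activation transcription factors 23 rose and 2 fell (23 and 2 adjusted over the list alone; camera adjusted p = 1.0e-14, adjusted p = 0.020 with an estimated correlation), led by Nr4a1 (7.58), Egr3 (7.52) and Atf3 (7.07). NF-kB pathway genes rose in 16 of 20 cases and fell in 2 (16 and 3 adjusted over the list alone; camera adjusted p = 6.2e-08, adjusted p = 0.048 with an estimated correlation). All 32 ribosome biogenesis genes rose (32 adjusted over the list alone; camera adjusted p = 1.7e-20, adjusted p = 0.024 with an estimated correlation). So did 16 of 18 genes of the integrated stress response and amino acid uptake (16 adjusted over the list alone; camera adjusted p = 4.3e-14, adjusted p = 0.020 with an estimated correlation), such as Asns (5.23) and Chac1 (4.95). Costimulatory and activation receptors had 10 of 18 genes higher and 3 lower (11 and 4 adjusted over the list alone; camera adjusted p = 4.7e-05, adjusted p = 0.051 with an estimated correlation), including Tnfrsf9 (4.88) and Slamf1 (4.39). Inhibitory receptors had 6 of 12 higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.0084, adjusted p = 0.091 with an estimated correlation), including Havcr2 (4.80) and Pdcd1 (4.79). Negative regulators of T cell signalling had 18 of 32 higher and 9 lower (18 and 9 adjusted over the list alone; camera adjusted p = 0.0019, adjusted p = 0.19 with an estimated correlation), including Rgs16 (6.21) and Spry1 (4.95).

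Genes of the interferon response and of the memory state fell in stimulated memory cells. Of 25 type I interferon stimulated genes 19 fell and 1 rose (19 and 1 adjusted over the list alone; camera adjusted p = 3.6e-07, adjusted p = 0.084 with an estimated correlation), with Oas3 at -4.91 (SE 0.29), Mx1 at -4.42 (SE 0.29) and Xaf1 at -3.78 (SE 0.13). Of 22 memory and naive associated genes 13 fell and 2 rose (15 and 3 adjusted over the list alone; camera adjusted p = 0.0039, adjusted p = 0.23 with an estimated correlation), including Klf3 (-3.87), S1pr1 (-3.55) and Cd55 (-2.48). Cytotoxic effector molecules had 5 of 19 genes higher and 10 lower (5 and 10 adjusted over the list alone; camera adjusted p = 0.41). Effector differentiation genes had 5 of 20 higher and 9 lower (5 and 9 adjusted over the list alone; camera adjusted p = 0.82). Among killer cell lectin-like and NK receptors 1 of 14 rose and 6 fell (1 and 6 adjusted over the list alone), with a camera adjusted p of 0.091, or 0.042 without memory ex vivo replicate 2. Cell cycle S phase had 2 of 31 genes higher and 11 lower (2 and 11 adjusted over the list alone; camera adjusted p = 0.10). G2 and M phase had 1 of 34 higher and 10 lower (1 and 9 adjusted over the list alone; camera adjusted p = 0.20).

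Between stimulated and ex vivo memory cells 6618 genes passed, 2566 higher and 4052 lower, of which 3436 differed at least 2-fold. In 5577 of them, and in each gene named here as changed in this comparison, the arrays of the groups were separate, as in 5961 of all 15487 genes, where chance alone would give 2.86% of the 15487. Without memory stimulated replicate 1 there were 4363 higher and 4373 lower genes, and without replicate 4 there were 3576 and 4295. The median of all genes was 0.09 log2 units, and -0.01 when arrays were shifted to a common median. Among markers of other cells 4 of 14 B cell genes fell, 1 of 15 macrophage, monocyte and dendritic cell genes rose and 4 fell, and 1 of 5 erythroid genes rose. Of 4 NK cell genes 3 fell (camera adjusted p = 0.071, or 0.042 without memory ex vivo replicate 2 and 0.045 without memory stimulated replicate 3). In addition 2 of 7 platelet genes rose and 1 fell, and 1 of 9 stromal and endothelial genes rose and 1 fell. These 3 rises were absent (0 and 0) without memory stimulated replicates 2 and 3. None of 7 neutrophil markers passed in limma (0 at an unadjusted p under 0.05, fry adjusted p = 0.25). Of 9 CD4 T cell markers 3 rose (camera adjusted p = 0.036, adjusted p = 0.10 with an estimated correlation, 0.061 without memory stimulated replicate 4, 0.47 without genes of other lists, from 3.8e-08 to 0.47 over 30 settings). Paired by mouse in a fixed block, 5916 genes passed. Without memory stimulated replicates 2 and 3 the count was 6764, which shared 5538 genes with the 6618, and with the actin signal ratio as a covariate it was 3422, both alternatives chosen after seeing the data.

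The responses of effector and memory cells overlapped. Of the 1628 genes that rose in effector cells, 1308 rose in memory cells, against 269.7 for independent lists, and of the 2601 that fell, 2256 fell in memory cells, against 680.5. Both comparisons share each gene's residual spread, the culture step and any array batch. These can raise the overlap by themselves, so independent lists are not a strict reference. Among the 3579 genes past the threshold in both, 15 went in opposite directions. Across genes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.839 and a Spearman correlation of 0.724.

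**Figure D3:**
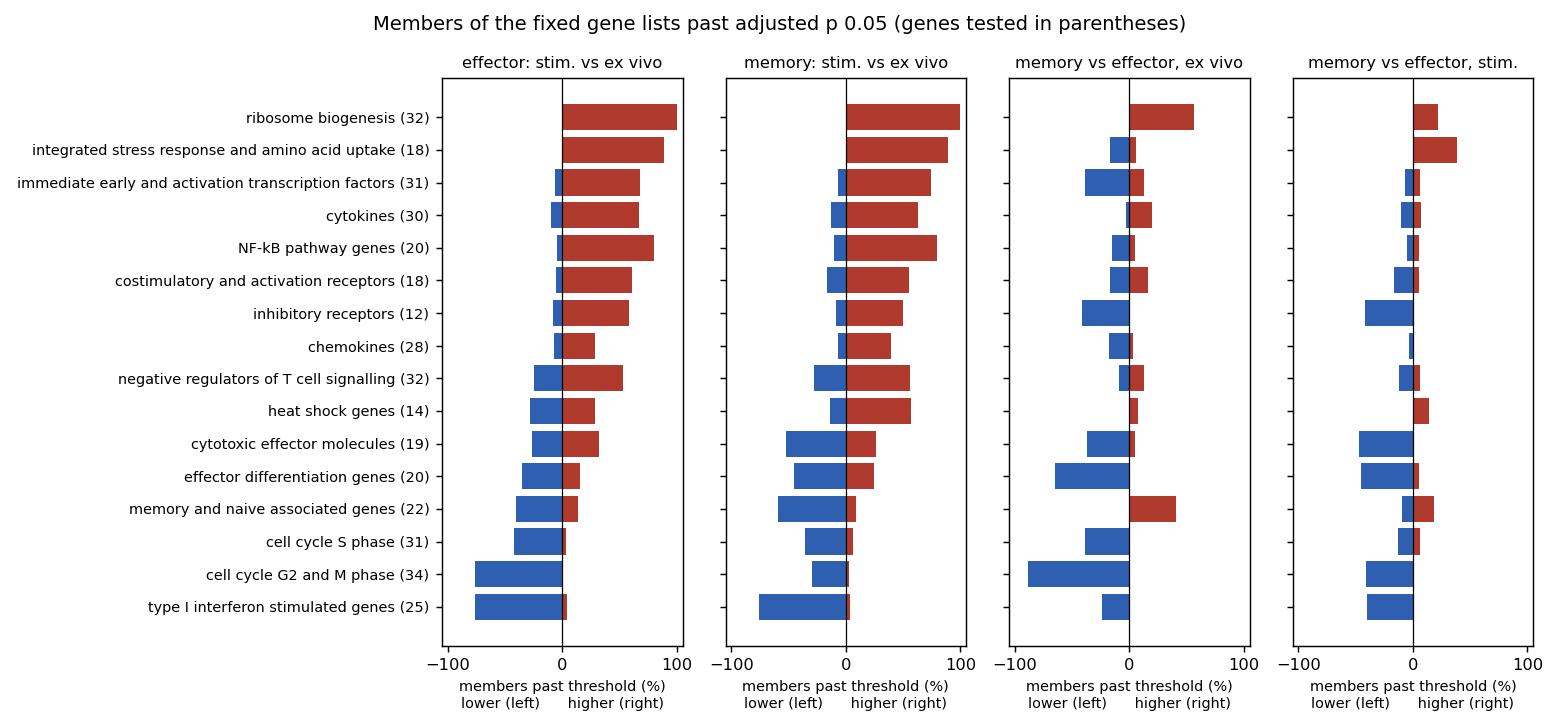
Percentage of the tested members of 16 fixed gene lists past the threshold in each of 4 comparisons, with higher members to the right and lower members to the left of 0 and the number tested in parentheses. All 32 ribosome biogenesis genes rose upon stimulation in both cell types, and 30 of 34 G2 and M phase genes were lower in memory than effector cells ex vivo.

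Memory and effector cells were compared ex vivo to ask how the resting state of memory cells differs from that of cells at the peak of the response. Cell cycle genes were lower in memory cells, in 30 of 34 G2 and M phase genes (33 adjusted over the list alone; camera adjusted p = 4.7e-44, adjusted p = 0.040 with an estimated correlation). The difference was -3.89 (SE 0.42, n = 4 and 3) for Ube2c, -3.77 (SE 0.33) for Ccnb2 and -3.33 (SE 0.35) for Mki67, the gene of the proliferation marker Ki-67. In S phase 12 of 31 were lower (19 adjusted over the list alone; camera adjusted p = 4.9e-11, adjusted p = 0.061 with an estimated correlation), such as E2f1 (-1.79). Of 20 effector differentiation genes 13 were lower (14 adjusted over the list alone; camera adjusted p = 3.6e-15, adjusted p = 0.040 with an estimated correlation), including Havcr2 (-3.28, SE 0.22), granzyme B (Gzmb, -2.50, SE 0.22) and Cx3cr1 (-2.21, SE 0.32). Of 22 memory and naive associated genes 9 were higher in memory cells (9 adjusted over the list alone; camera adjusted p = 2.4e-06, adjusted p = 0.085 with an estimated correlation), including the survival factor Bcl2 (2.28, SE 0.29) and Il7r (1.80, SE 0.14).

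Chemokine transcripts differed in both directions ex vivo, with 1 of 28 higher and 5 lower in memory cells (1 and 6 adjusted over the list alone; camera adjusted p = 0.27). Xcl1 was higher in memory cells by 2.25 log2 units (SE 0.15, adjusted p = 4.8e-06), with mean signals of 6.42 (SD 0.08, n = 4) against 4.17 (SD 0.39, n = 3). Lower in memory cells were Ccl3 (-1.85, SE 0.20, adjusted p = 8.6e-05), Ccl4 (-0.76, SE 0.14, adjusted p = 0.0042) and Ccl6 (-0.98, SE 0.21, adjusted p = 0.012, 0.059 without effector ex vivo replicate 1, from 0.0010 to 0.059 over 30 other settings). The call of Ccl9 (-0.62, SE 0.17, adjusted p = 0.041) was lost in 16 of 30 other settings, over which adjusted p ranged from 0.0038 to 0.71. It was lost without effector ex vivo replicates 1, 2 and 3 (adjusted p = 0.17, 0.051 and 0.16), effector stimulated replicates 1, 2 and 3 (0.061, 0.062 and 0.059), memory ex vivo replicates 2 and 4 (0.11 and 0.11) or memory stimulated replicate 4 (0.052). Ccl5 differed by -0.31 (SE 0.10, adjusted p = 0.095), with adjusted p = 0.044 without memory stimulated replicate 1 and a range from 0.010 to 0.31.

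Several other groups differed ex vivo. Of 31 immediate early and activation transcription factors 12 were lower in memory cells and 4 higher (14 and 4 adjusted over the list alone; camera adjusted p = 7.4e-07, adjusted p = 0.061 with an estimated correlation), including Nr4a1 (-2.69, SE 0.13), Nr4a2 (-2.33) and Irf4 (-2.27). Of 12 inhibitory receptors 5 were lower (6 lower and 2 higher adjusted over the list alone; camera adjusted p = 4.3e-04, adjusted p = 0.048 with an estimated correlation), such as Ctla4 (-2.19) and Pdcd1 (-1.66). That call was lost when genes held by another list were left out (adjusted p = 0.18, from 3.8e-05 to 0.18 over 30 settings). Cytotoxic effector molecules had 7 of 19 genes lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 6.6e-04, adjusted p = 0.11 with an estimated correlation). Of 14 killer cell lectin-like and NK receptors 5 were lower (6 lower and 1 higher adjusted over the list alone). Their camera adjusted p was 0.012, or 0.053 without effector ex vivo replicate 1 and 0.11 without genes of other lists, and adjusted p = 0.15 with an estimated correlation (from 0.0069 to 0.15 over 30 settings). Ribosome biogenesis genes were higher in memory cells in 18 of 32 cases (19 adjusted over the list alone; camera adjusted p = 1.1e-17, adjusted p = 0.040 with an estimated correlation), such as Nop2 (1.43) and Utp20 (1.20). Of 25 type I interferon stimulated genes 6 were lower (8 adjusted over the list alone; camera adjusted p = 1.5e-06, adjusted p = 0.085 with an estimated correlation), such as Ifi27l2a (-2.26). Cytokines had 6 of 30 genes higher and 1 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.059), including Il15 (1.16) and Lta (1.04). Camera called cytokines higher without effector ex vivo replicate 1 (adjusted p = 0.048), effector stimulated replicate 1 (0.047), or memory ex vivo replicates 1 (0.050) or 2 (0.042). The largest single differences were those of Dmrta1 (4.99, SE 0.42) and the protease gene Prss12 (4.59, SE 0.31), higher in memory cells.

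Ex vivo, 1175 genes passed, 582 higher and 593 lower in memory cells, of which 495 differed at least 2-fold. In 1170 of them, and in each gene named here as different, the arrays of the groups were separate. Over all 15487 genes this held in 4499, where chance alone would give 5.71%. None of the 14 B cell, 7 neutrophil, 5 erythroid, 7 platelet and 9 stromal and endothelial markers passed in limma (1, 0, 1, 0 and 0 at an unadjusted p under 0.05, fry adjusted p from 0.40 to 0.85), while 1 of 15 macrophage, monocyte and dendritic cell genes was lower and 1 of 4 NK cell genes higher. Of 9 CD4 T cell markers 2 were lower (camera adjusted p = 0.076, or 0.044 without effector ex vivo replicate 3 and 0.037 without memory ex vivo replicate 4). The count was 649, 750 and 770 without effector ex vivo replicate 3, effector ex vivo replicate 1 and memory ex vivo replicate 2, and 2194 without memory stimulated replicate 2. Without effector ex vivo replicate 2, 382 rather than 593 genes were lower. The count was 775 with arrays shifted to a common median, and 2914, with all 1175 among them, without memory stimulated replicates 2 and 3. The median SD of a gene was 0.125 and 0.146 in the 2 groups compared, against 0.380 in memory stimulated cells. The spread shared by the 4 groups can thus make SEs too large and the count too small, here and in the effector response. Fitted to the arrays of these 2 groups alone, 3069 genes passed in limma.

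Memory and effector cells were then compared after stimulation, to ask how far their activated states differ. The chemokine transcripts that rose upon stimulation had no difference past the threshold. The difference was -0.40 for Ccl1 (SE 0.16, adjusted p = 0.12), -0.09 for Ccl3 (SE 0.20, adjusted p = 0.77), -0.16 for Ccl4 (SE 0.14, adjusted p = 0.43), 0.24 for Ccl9 (SE 0.17, adjusted p = 0.32) and -0.08 for Xcl1 (SE 0.15, adjusted p = 0.71), where the group means lay between 11.4 and 12.7. The means of Ccl3, Ccl4 and Xcl1 in both cell types, and of Ccl1 in effector cells, lay within 2 log2 units of the lowest array maximum of 13.75, where differences can be compressed, so equal levels are not shown. Of 28 chemokines 1 passed, Ccl5 (-0.37, SE 0.10, adjusted p = 0.034), and 0 passed adjusted over the list alone (camera adjusted p = 0.37). The call of Ccl5 was lost in 16 of 30 other settings, over which adjusted p ranged from 0.0033 to 0.25. It was lost without effector stimulated replicates 1, 2 and 3 (adjusted p = 0.13, 0.067 and 0.11), memory stimulated replicates 3 and 4 (0.082 and 0.051), effector ex vivo replicates 2 and 3 (0.050 and 0.050) or memory ex vivo replicates 2, 3 and 4 (0.053, 0.051 and 0.051). Ccl1 was lower in memory cells without memory stimulated replicate 3 (adjusted p = 0.017), with a range from 0.013 to 0.86 over the settings.

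After stimulation, cytotoxic and effector differentiation genes were lower in memory cells, and 5 cytotoxic and 6 effector differentiation genes were lower both ex vivo and after stimulation. Of 19 cytotoxic effector molecules 9 were lower (10 adjusted over the list alone; camera adjusted p = 3.8e-06, adjusted p = 0.23 with an estimated correlation), including granzymes A (Gzma, -2.57, SE 0.37, n = 4 and 3) and B (Gzmb, -2.55, SE 0.22). Effector differentiation genes had 9 of 20 lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 5.6e-05, adjusted p = 0.23 with an estimated correlation), including Prdm1 (Blimp-1, -2.33) and Batf (-2.18). Without genes of other lists this list was not called (adjusted p = 0.27, from 1.1e-05 to 0.27 over 30 settings). Of 12 inhibitory receptors 5 were lower (5 adjusted over the list alone; camera adjusted p = 0.0080, adjusted p = 0.23 with an estimated correlation), such as Cd200 (-3.81, SE 0.43) and Ctla4 (-1.94), a call lost without genes of other lists (adjusted p = 0.11, from 4.9e-04 to 0.23 over 30 settings). Among 14 killer cell lectin-like and NK receptors 4 were lower (4 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.23 with an estimated correlation). This call was lost without effector stimulated replicate 1 (adjusted p = 0.051) or memory stimulated replicate 4 (0.059). G2 and M phase genes were lower in 14 of 34 cases (24 adjusted over the list alone; camera adjusted p = 1.2e-12, adjusted p = 0.24 with an estimated correlation), such as Mki67 (-3.33, SE 0.35). In S phase 4 of 31 were lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.049, adjusted p = 0.77 with an estimated correlation), with Rrm2 at -4.00. The S phase call was lost in 16 of 30 other settings, over which camera adjusted p ranged from 0.012 to 0.77. Among these were the fits without effector stimulated replicate 3 (adjusted p = 0.13), memory ex vivo replicates 1 (0.054) or 4 (0.050), memory stimulated replicates 2 (0.14) or 4 (0.059), or genes of other lists (0.057). Of 25 type I interferon stimulated genes 10 were lower (13 lower and 2 higher adjusted over the list alone; camera adjusted p = 5.6e-05, adjusted p = 0.23 with an estimated correlation), such as Ifi27l2a (-2.36) and Xaf1 (-2.14).

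Higher in stimulated memory cells were 7 of 18 genes of the integrated stress response and amino acid uptake (9 adjusted over the list alone; camera adjusted p = 5.6e-05, adjusted p = 0.23 with an estimated correlation), such as Slc3a2 (0.70, SE 0.11). So were 7 of 32 ribosome biogenesis genes (8 adjusted over the list alone; camera adjusted p = 5.6e-05, adjusted p = 0.27 with an estimated correlation), such as Rrp9 (0.86, SE 0.14). The actin covariate overlaps with the memory stimulated group, so calls lost with it do not separate RNA length from the group difference. With the actin covariate, chosen after seeing the data, the calls of Slc3a2 (0.54, adjusted p = 0.14, from 4.3e-04 to 0.14 over 30 settings), Rrp9 (0.46, 0.20, from 0.0012 to 0.20) and Gzma (-1.95, 0.10, from 1.8e-04 to 0.10) were lost. In the fit of these 7 arrays alone Slc3a2 (adjusted p = 0.050), Rrp9 (0.062), Prdm1 (0.073, from 4.3e-06 to 0.073) and Ctla4 (0.058, from 4.5e-04 to 0.058) lost theirs. Cytokines had 2 of 30 genes higher and 3 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.38), with Tnfsf11 at 1.84 (SE 0.20), Il10 at -2.48 (SE 0.39; adjusted p = 0.077 in the fit of these arrays alone, from 4.0e-05 to 0.077 over 30 settings) and Il13 at -1.53 (SE 0.15). Il21 differed by -2.42 (SE 0.77, adjusted p = 0.062), and passed without memory stimulated replicate 1 (adjusted p = 0.033), 2 (0.0032) or 4 (0.031), with a range from 0.0026 to 0.30 over 30 settings. Memory and naive associated genes had 4 of 22 higher and 2 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.37), including Il7r (1.42) and Bcl6 (1.24). Of 31 immediate early and activation transcription factors 2 were higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.25). Of 18 costimulatory and activation receptors 1 was higher and 3 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.57). Among 20 NF-kB pathway genes 1 was higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.80), and among 32 negative regulators of T cell signalling 2 were higher and 4 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.38).

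After stimulation 1669 genes passed, 463 higher and 1206 lower in memory cells, of which 703 differed at least 2-fold. The arrays of the groups were separate in 1623 of them and in each gene named here as different. Among all 15487 genes they were separate in 3672, where chance alone would give 5.71%. The markers of B cells (1 of 14), macrophages, monocytes and dendritic cells (3 of 15), CD4 T cells (3 of 9) and platelets (1 of 7) that passed were lower in memory cells, and 1 of 9 stromal and endothelial markers was higher. Without memory stimulated replicates 2 and 3 this last number was 0, and 2 rather than 3 macrophage, monocyte and dendritic cell markers were lower. Camera called the CD4 T cell markers lower without memory stimulated replicate 2 (adjusted p = 0.046, against 0.081 with it). None of the 7 neutrophil, 5 erythroid and 4 NK cell markers passed in limma (0 at an unadjusted p under 0.05, fry adjusted p = 0.39, 0.39 and 0.79). With quantile or cyclic loess scaling 1033 genes were higher and 1109 lower, or 1161 higher and 1137 lower. The median SD of a gene was 0.380 in memory stimulated cells, against 0.125 to 0.146 in the other groups. A spread shared by the 4 groups can thus make SEs too small and the count too large, here and in the memory response. The count after stimulation was 235 when limma was fitted to these 7 arrays alone and 247 with the actin signal ratio as a covariate. Without effector stimulated replicates 1, 2 and 3 it was 856, 1004 and 755, and without memory stimulated replicates 1 and 4 it was 3348 and 2773. Without memory stimulated replicate 2, 851 rather than 463 genes were higher. Without memory stimulated replicates 2 and 3 together it was 2526, of which 1418 were among the 1669.

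The interaction asked which genes responded to stimulation differently in memory and effector cells. Among the 329 genes past the threshold, 59 rose in both and more in memory cells, and 71 fell in both and more in memory cells. Another 25 rose in both but less in memory cells, and 14 fell in both but less in memory cells. In effector cells only, 32 rose and 32 fell past the threshold, and in memory cells only, 18 rose and 64 fell. The directions were opposite for 5 genes that rose and 9 that fell in memory cells. Transcription factors of early activation rose more in memory cells: Nr4a1 by a further 3.00 log2 units (SE 0.18, adjusted p = 9.2e-06), Nr4a2 by 2.29 (SE 0.15) and Egr3 by 2.00 (SE 0.17). These larger rises mirror lower ex vivo means in memory than effector cells, 3.59 against 6.28, 5.91 against 8.23 and 3.93 against 5.89. After stimulation the means in memory and effector cells were 11.2 and 10.9, 11.6 and 11.7, and 11.5 and 11.4. Of 31 immediate early and activation transcription factors 10, among them Irf4, whose other probe set had the opposite sign (-1.01), had a higher and 1 a lower response in memory cells (11 and 2 adjusted over the list alone; camera adjusted p = 2.3e-07, adjusted p = 0.24 with an estimated correlation). Among 28 chemokines the response of Ccl3 was higher in memory cells (1.76, SE 0.28, adjusted p = 0.0080) and that of Xcl1 lower (-2.33, SE 0.21, adjusted p = 1.9e-04), and 3 higher and 1 lower passed adjusted over the list alone. The list had a camera adjusted p of 0.065, or 0.050, 0.045 and 0.045 without effector ex vivo replicate 2 and memory ex vivo replicates 1 and 4. Those of Ccl1 (-0.32, adjusted p = 0.47), Ccl4 (0.61, adjusted p = 0.15), Ccl5 (-0.06, adjusted p = 0.82) and Ccl9 (0.86, adjusted p = 0.086) did not pass. The differing responses of Ccl3 and Xcl1 mirror their ex vivo differences of -1.85 and 2.25, and their stimulated means lay within 1.23 log2 units of the lowest array maximum, so an upper limit of the signal is not excluded for them.

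**Figure D4:**
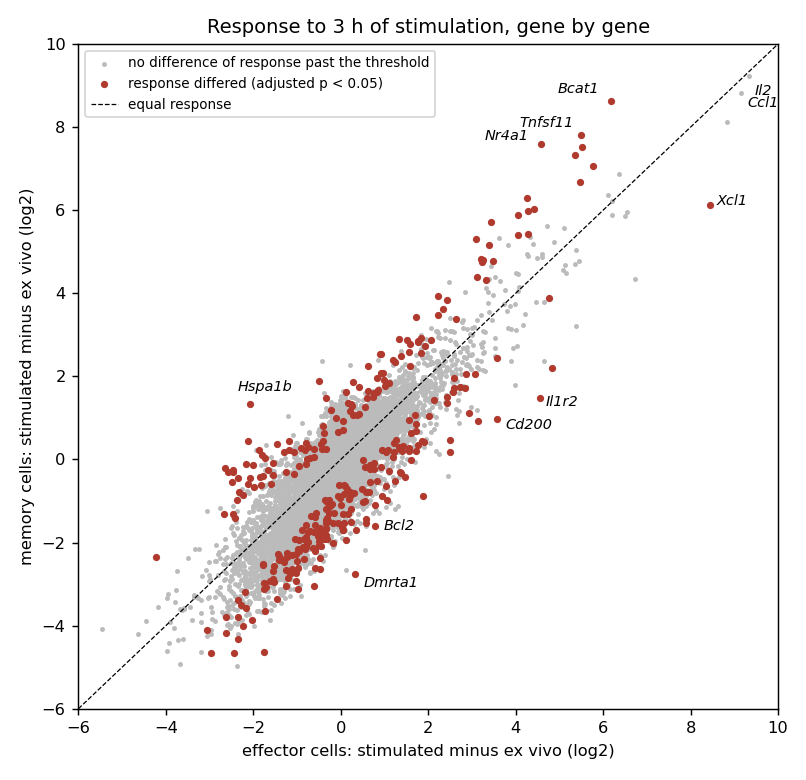
Log2 difference between stimulated and ex vivo cells for each of 15487 genes, effector cells on the horizontal and memory cells on the vertical axis, with the 329 genes whose response differed in red and equal responses on the dashed line. Il2 and Ccl1 lie near the line at 9.32 and 9.23, and at 9.14 and 8.83, while Nr4a1 (4.58 and 7.58) lies above it and Xcl1 (8.44 and 6.11) below it.

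Other genes also differed in their response. The response of the survival gene Bcl2 was lower in memory cells (-2.37, SE 0.41), which mirrors its higher ex vivo signal there (a difference of 2.28). The responses of Cd70, a costimulatory ligand (-2.62, SE 0.39), and the decoy receptor gene Il1r2 (-3.05, SE 0.51) were lower in memory cells too. The responses of Tnfsf11 (2.31, SE 0.29) and of the heat shock gene Hspa1b (3.41, SE 0.47), whose signal fell in effector and rose in memory cells, were higher. The call of the rise of Hspa1b in memory cells was lost in 1 of 30 other settings. G2 and M phase genes had a higher response in 5 of 34 cases (12 adjusted over the list alone; camera adjusted p = 1.6e-09, adjusted p = 0.56 with an estimated correlation), such as Hmmr (2.06). Its mean signal fell from 5.72 to 3.57 in effector cells and was at 2.90 and 2.80, near the background, in memory cells. S phase genes had 3 of 31 higher (4 adjusted over the list alone; camera adjusted p = 0.0074, adjusted p = 0.56 with an estimated correlation), a call lost without memory stimulated replicates 1 (adjusted p = 0.078) or 4 (0.050). The integrated stress response and amino acid uptake list had 5 of 18 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 7.0e-05, adjusted p = 0.31 with an estimated correlation), such as Slc3a2 (1.16). Cytokines had a lower response in memory cells (1 of 30 higher and 2 lower, 1 and 6 adjusted over the list alone; camera adjusted p = 0.027, adjusted p = 0.52 with an estimated correlation). That call was lost without effector stimulated replicate 2 (adjusted p = 0.060), memory stimulated replicate 4 (0.050) or genes of other lists (0.089), with a range from 0.0071 to 0.52 over 29 settings. The response was also lower for memory and naive associated genes (1 of 22 lower, 6 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.56 with an estimated correlation). For ribosome biogenesis 2 of 32 were lower (6 adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.56 with an estimated correlation). The call of memory and naive associated genes was lost in 4 and that of ribosome biogenesis in 5 of 29 other settings.

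The interaction count was 128 higher and 201 lower in memory cells, and 266 and 275 with quantile scaling. It was 161 genes with arrays shifted to a common median and 87 with the actin signal ratio as a covariate. With that covariate the calls of Bcl2 (-2.21, adjusted p = 0.073, from 0.0029 to 0.073 over 29 settings) and Cd70 (-2.28, 0.051, from 1.9e-04 to 0.051) were lost. Paired by mouse in a fixed block it was 79 rather than 329, with 48 higher and 31 lower. Nr4a1, Hspa1b, Xcl1, Bcl2 and Ccl3 passed in this fit. The calls of Il1r2 (adjusted p = 0.056, from 5.8e-05 to 0.056 over 29 settings), Dmrta1 (0.086, from 2.6e-04 to 0.086), Cd200 (0.11, from 0.011 to 0.17), Ccnb2 (0.076, from 0.0060 to 0.098), Psat1 (0.076, from 9.3e-04 to 0.076) and Ubash3a (0.076, from 0.0020 to 0.076) were lost in it. Without effector ex vivo replicates 1, 2 and 3 the count was 145, 214 and 145, without effector stimulated replicates 1, 2 and 3 147, 178 and 166, and without memory ex vivo replicates 1, 2, 3 and 4 189, 159, 202 and 169. The count was 550, 847, 226 and 577 without memory stimulated replicates 1, 2, 3 and 4. Without replicate 3, 131 rather than 201 genes had a lower response in memory cells. Without memory stimulated replicates 2 and 3 together the count was 1103, with all 329 among them. The call of Hmmr was lost without effector stimulated replicates 1 or 2 (adjusted p = 0.056 and 0.058) or memory ex vivo replicate 4 (0.052), with a range from 0.0050 to 0.073 over 29 settings.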

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

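The tests of lost moderate transcripts, of the upper end of the array, of handling stress, of scaling between arrays and of days assigned to whole mice, and the alternative without memory stimulated replicates 2 and 3, were chosen after the result was seen. In 13 of 278 groups of 4 arrays (4.68%) an array lay apart from the others, by a gap that took more of the group's range than Dixon's 95% value for 4 allows, and chance gives about 1 in 20. Ex vivo in memory cells, replicate 2 was lowest for Gzma (0.912; 9.17 against a mean of 10.6 for the others), Irf4 (0.862) and Serpinb6b (0.856). Replicate 1 was lowest for Ifng (0.923) and Tnfsf10 (0.845) and highest for Racgap1 (0.857). In stimulated memory cells replicate 2 was lowest for Dusp4 (0.840), Il1r2 (0.939), Il21 (0.869; 3.95 against a mean of 7.84), Nsg2 (0.920) and Rpl12 (0.923). Replicate 1 was highest for Racgap1 (0.864) and Rrp9 (0.934).

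Memory stimulated replicates 2 and 3 had interquartile ranges of 2.11 and 2.58, against at least 3.18 on the other arrays. Replicate 1, which serves below as a reference with replicate 4, had the largest 3' minus 5' signals of the 14 arrays, 1.88 for beta-actin and 1.83 for Gapdh. In replicate 4 they were 1.26 and 1.23. A weaker response of the cells of replicate 2 cannot be told apart from other causes: the slope of its response on that of replicates 1 and 4 was 0.756 for rising and 1.28 for falling genes, and their difference of -0.524 passed the bound of 0.5 set for its absence, but a narrow range by itself steepens the fall of moderate genes, a reason found after these values were seen. Marker lists gave no sign of cells of another type, since the highest of the 8 lay at percentile 81.66 of 10000 random lists matched on level. A median over 4 to 15 genes can miss a rise of a few of them, so such cells are not excluded. Loss of moderately expressed transcripts in replicate 2 cannot be told apart from other causes: 779 genes of level 5 to 8 had a median deviation of -1.07, but the third quartile of that array was 5.07 against 5.93 and 5.99 in replicates 1 and 4, so genes of this level had to lie lower. A general dimming of bright transcripts cannot be told apart from none, although 576 bright genes deviated by -0.054 and -0.0040 in replicates 2 and 3, within the bound of 0.2 set for its absence, because scaling between arrays held the 99th percentiles of the 14 arrays within 0.105 log2 units, a reason found after these values were seen.

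The response to stimulation differed between memory and effector cells, by the test of the interaction, in 329 genes. Responses were higher in memory cells for Hspa1b (3.41), Nr4a1 (3.00), Bcat1 (2.45), Tnfsf11 (2.31), Nr4a2 (2.29), Irf4 (2.22), Ccnb2 (2.21), Aurkb (2.10), Hmmr (2.06) and Egr3 (2.00). They were also higher for Ccl3 (1.76), Dusp2 (1.72), Havcr2 (1.54), Rel (1.34), Pdcd1 (1.30), Slamf1 (1.28), Trib3 (1.26), Slc3a2 (1.16) and Psat1 (1.09). A higher response need not be a rise in memory cells. Of the genes with a higher response, 32 fell in effector cells without passing in memory cells, and 14 fell in both but less in memory cells. Ccnb2 and Hmmr fell in effector cells and had lower ex vivo signals in memory cells. The call of Rel was lost in 1 of 29 other settings. Responses were lower for Dmrta1 (-3.08), Il1r2 (-3.05), Cd70 (-2.62), Cd200 (-2.59), Bcl2 (-2.37), Xcl1 (-2.33) and Ubash3a (-2.15). The other probe sets of Bcat1 (-0.47 and -0.34) and Irf4 (-1.01) had the opposite sign without passing, and with the mean of a gene's probe sets both calls were lost (adjusted p = 0.36, from 9.8e-05 to 0.36 over 29 settings, and 0.38, from 3.8e-06 to 0.38), so a stronger response of these 2 genes is not shown. Camera called 9 lists for a differing response, and 0 of them with an estimated correlation (adjusted p = 0.28 for heat shock and 0.60 for cytosolic ribosomal proteins). These lists had median differences of 1.04 (G2 and M phase), 0.49 (integrated stress response), 0.47 (immediate early and activation factors), 0.30 (S phase) and 0.30 (heat shock). The medians were -0.57 (memory and naive associated genes), -0.36 (cytokines), -0.18 (ribosome biogenesis) and -0.094 (cytosolic ribosomal proteins). Without memory stimulated replicates 2 and 3 all 9 medians kept their sign, but that of memory and naive associated genes was -0.29 and that of S phase 0.54.

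Some of these calls of a differing response lay near the threshold and were lost when any of several single arrays was left out, with adjusted p in parentheses and its range over the other settings after it. Cd200 lost its call without effector ex vivo replicates 1, 2 and 3 (0.13, 0.076 and 0.12), effector stimulated replicates 1, 2 and 3 (0.10, 0.11 and 0.11), memory ex vivo replicates 1, 2, 3 and 4 (0.087, 0.094, 0.075 and 0.063) or memory stimulated replicate 3 (0.087), and ranged from 0.011 to 0.17. Trib3 lost its call without effector ex vivo replicates 1, 2 and 3 (0.069, 0.068 and 0.11), effector stimulated replicates 1, 2 and 3 (0.078, 0.088 and 0.068), memory ex vivo replicates 1, 2 and 4 (0.063, 0.074 and 0.057) or memory stimulated replicate 3 (0.051), and ranged from 0.0041 to 0.45. Aurkb lost its call without effector ex vivo replicates 1 and 3 (0.070 and 0.086), effector stimulated replicates 1 and 2 (0.10 and 0.092), memory ex vivo replicates 1, 2, 3 and 4 (0.077, 0.078, 0.062 and 0.069) or memory stimulated replicate 3 (0.071), and ranged from 0.0089 to 0.10. Havcr2 lost its call without effector ex vivo replicates 1, 2 and 3 (0.054, 0.057 and 0.086), effector stimulated replicates 1, 2 and 3 (0.054, 0.065 and 0.077), memory ex vivo replicates 2 and 4 (0.055 and 0.060) or memory stimulated replicate 3 (0.051), and ranged from 0.0017 to 0.11. Ccnb2 lost its call without effector ex vivo replicates 1 and 3 (0.073 and 0.098), effector stimulated replicates 1 and 2 (0.098 and 0.088) or memory ex vivo replicates 1, 2 and 4 (0.067, 0.072 and 0.071), and ranged from 0.0060 to 0.098. Dmrta1 lost its call without effector ex vivo replicates 1 and 3 (0.052 and 0.074), effector stimulated replicates 2 and 3 (0.058 and 0.067) or memory ex vivo replicate 2 (0.051), and ranged from 2.6e-04 to 0.086. Pdcd1 lost its call without effector stimulated replicates 1 and 3 (0.054 and 0.066) or memory ex vivo replicate 4 (0.052), and ranged from 0.0035 to 0.10. The list of cytosolic ribosomal proteins lost its call without effector ex vivo replicate 1 (0.096), effector stimulated replicates 2 and 3 (0.060 and 0.059), memory ex vivo replicate 2 (0.072) or memory stimulated replicates 2, 3 and 4 (0.061, 0.083 and 0.071).

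Of the immediate early and activation factors, 10 passed for a stronger rise in memory cells (median 1.73; 1.61 for the 9 other than Irf4, for which it is not shown), 9 of which were lower in memory cells ex vivo (median of the 10, -1.43; 8 and -1.42 without Irf4) and 1 of which differed after stimulation (median 0.08; 0.12 without Irf4). Signal near the upper end of the array was argued against as the whole cause, since 7 of the 10, and 7 of the 9 other than Irf4, lay more than 2 log2 units under the lowest array maximum of 13.75 after stimulation. The narrow range of memory stimulated replicates 2 and 3 was argued against as well, since the median was 1.80 without these arrays, and 1.65 without Irf4 too. Handling stress in effector cells ex vivo cannot be told apart from other causes: 16 handling genes had a median difference of -0.127, between the bounds set for its presence (-0.5) and absence (0), 0 were lower in memory cells by limma (3 at an unadjusted p under 0.05) and 1, Ier3, was higher. The handling genes include Fos, Fosb, Jun, Junb, Jund, Ier2, Ier3 and Atf3 of the list of activation factors. Atf3 is among the 10, so the 2 sets are not independent. A difference between the days, such as recent antigen contact at day 8, stays open and untested.

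Interferon stimulated genes fell upon stimulation by median differences of -1.53 in effector and -1.3 in memory cells, where the call of the list was lost with an estimated correlation (adjusted p = 0.084; 0.029 in effector cells). Scaling between arrays was argued against, since at least 92.4% of the median was kept under 3 other scalings. A general fall of genes at that ex vivo level was argued against too: the list lay at percentile 0 in effector and 0.01 in memory cells of 10000 random lists matched on level, whose medians were -0.14 and -0.27. The 3 h in culture cannot be told apart from the stimulation, since 0 arrays were of cells cultured without it, and an effect of receptor stimulation itself stays open.

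Control probe sets and unnamed probe sets were not part of the comparisons. The 3' signal exceeded the 5' signal by 1.00 log2 units for beta-actin in effector stimulated cells, and by 1.48 for beta-actin and 1.51 for Gapdh in memory stimulated cells. Of 6521 unnamed probe sets tested, 1112 passed for effector stimulation (693 higher) and 1835 for memory stimulation (698 higher).

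With limma fitted to the arrays of the groups compared, 6470 genes passed for effector stimulation and at most 0 in the 9 other splits, but 10 splits are too few for a share under 0.05. For memory stimulation 5072 genes passed and at most 0 in other splits of 35, of which the 8 that part all pairs of same-numbered arrays are too few for a share under 0.05. For memory against effector cells ex vivo 3069 genes passed and at most 1 in other splits of 35. After stimulation 235 passed and at most 0 in other splits. In both, the real split was the only 1 of 35 with as many genes, the smallest share that 35 splits allow. Mixed splits hold the group difference in their residual spread, which lowers their counts. The 1175 and 1669 genes of the main fit were not tested in this way. For the interaction 329 genes passed, against at most 197 in 100 assignments of day within treatment that ignore pairs, the real one included. With pairs kept in blocks by mouse, 79 genes passed, against at most 2 in the other of 35 assignments of day to whole mice. The real assignment was the only 1 of 35 with as many genes.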

How the results depend on the processing

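The alternatives without memory stimulated replicates 2 and 3 and with the actin covariate were chosen after seeing the data, and the other tests of settings were planned. The counts are given in the order effector response, memory response, ex vivo comparison, comparison after stimulation and interaction where several are named. Scaling to a common median gave 775 genes ex vivo and 161 in the interaction, quantile scaling 541 and cyclic loess 573 in the interaction. Array weights gave 7032, 3492 and 1194 for the effector response, ex vivo and the interaction. Fits of only the 2 groups gave 6470, 3069 and 235 for the effector response, ex vivo and after stimulation. Testing every probe set gave 8379, 13400, 2175, 3503 and 519, because more features were tested. A 2-fold minimum gave 2381, 3436, 495 and 703 for the first 4 comparisons, and a threshold of 0.01 gave 592, 658 and 86 for the last 3, as stricter settings must lower a count. Blocks by mouse gave 79 in the interaction, with fewer residual degrees of freedom, and blocks by replicate number 780 ex vivo. Without memory stimulated replicates 2 and 3 the counts were 6396, 2914, 2526 and 1103 in all comparisons but the memory response. The actin covariate gave 3422 for the memory response, 247 after stimulation and 87 in the interaction, comparisons in which it overlaps with the memory stimulated group. Leaving out 1 array gave 3311 to 5689, 5621 to 8736, 649 to 2194, 755 to 3348 and 145 to 847. Apart from the constructions named, the cause was not tested.

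Higher genes after stimulation numbered 236 with a common median and 1004 with array weights, against 463. Other total counts stayed within 1.5 times the reported ones. Of 250 results of genes, 236 were called, and 0 of these called results reversed direction under any setting. A change of sign was not counted for results that were not called. Of the 250, calls were kept or stayed absent in 241 (median), 244 (quantile) and 245 (loess). They did so in 214 with the actin covariate and in 235 to 246 with 1 array left out. Of 150 list results, 59 were called by camera, and 0 of these called results reversed. Of all 150, 148, 144 and 142 kept their side of the threshold under the 3 scalings, and 108 with an estimated correlation. In the interaction Irf4 (adjusted p = 0.38), Bcat1 (0.36) and Slamf1 (0.064) lost their calls with the mean of a gene's probe sets, over settings with adjusted p from 3.8e-06 to 0.38 (Irf4), 9.8e-05 to 0.36 (Bcat1) and 3.7e-04 to 0.064 (Slamf1). Signals near the background compress the folds of dim genes.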

Other observations

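The alternative without memory stimulated replicates 2 and 3 was chosen after the result was seen, the other tests in this part were not, and the named genes were selected after their values were seen. Metabolic genes moved in both directions upon stimulation. Of 17 glycolysis genes 6 rose and 4 fell in effector cells (7 and 5 adjusted over the list alone; camera adjusted p = 0.36), and 8 rose and 4 fell in memory cells (9 and 5 adjusted over the list alone; camera adjusted p = 0.20). Hk2, hexokinase 2, rose by 2.20 (SE 0.16, n = 3 and 3) in effector and 3.09 (SE 0.14, n = 4 and 4) in memory cells. Of 20 cholesterol synthesis genes 1 rose and 6 fell in effector cells (1 and 7 adjusted over the list alone; camera adjusted p = 0.14), and 3 rose and 9 fell in memory cells (3 and 9 adjusted over the list alone; camera adjusted p = 0.19), with Dhcr7 at -2.94 (SE 0.30) and -3.66 (SE 0.26). Of 30 oxidative phosphorylation genes 2 rose and 4 fell in effector cells (2 and 4 adjusted over the list alone; camera adjusted p = 0.35), and 5 rose and 13 fell in memory cells (5 and 14 adjusted over the list alone; camera adjusted p = 0.19). Cycs, cytochrome c, rose by 1.40 (SE 0.12) and 1.73 (SE 0.11). Between memory and effector cells, camera called oxidative phosphorylation lower in memory cells ex vivo, with 1 gene higher and 2 lower (1 and 2 adjusted over the list alone; median -0.15, camera adjusted p = 0.012, adjusted p = 0.60 with an estimated correlation, fry adjusted p = 0.29, from 0.0015 to 0.60 over 30 settings). It did so after stimulation too, with 1 higher and 3 lower (1 and 9 adjusted over the list alone; median -0.25, camera adjusted p = 0.012, adjusted p = 0.77 with an estimated correlation, fry adjusted p = 0.19). These calls were lost in 5 and 8 of 30 other settings, the second also without memory stimulated replicates 2 and 3 (adjusted p = 0.43, from 0.0027 to 0.77). Cholesterol synthesis was called lower in memory cells ex vivo, with 0 genes higher and 1 lower (0 and 6 adjusted over the list alone; median -0.45, camera adjusted p = 0.0050, adjusted p = 0.16 with an estimated correlation). After stimulation 3 of its genes were lower (3 adjusted over the list alone; camera adjusted p = 0.051, from 0.019 to 0.45 over 30 settings).

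Chemokine receptors had 1 of 16 genes higher and 4 lower in stimulated effector cells (1 and 4 adjusted over the list alone; camera adjusted p = 0.41), and 3 higher and 4 lower in stimulated memory cells (3 and 4 adjusted over the list alone; camera adjusted p = 0.80), or 1 higher and 3 lower without memory stimulated replicates 2 and 3. Of 26 cytosolic ribosomal proteins 2 rose in effector cells (1 adjusted over the list alone; camera adjusted p = 0.72) and 5 were higher in memory than effector cells ex vivo (5 adjusted over the list alone; camera adjusted p = 2.3e-06, adjusted p = 0.085 with an estimated correlation). Of 14 heat shock genes 4 rose and 4 fell in effector cells (5 and 4 adjusted over the list alone; camera adjusted p = 0.76), and 8 rose and 2 fell in memory cells (9 and 2 adjusted over the list alone). The camera adjusted p in memory cells was 0.031, with adjusted p = 0.19 with an estimated correlation, 0.067 without memory stimulated replicate 1 and 0.058 without replicate 4. After stimulation 2 heat shock genes were higher in memory than effector cells (2 adjusted over the list alone; camera adjusted p = 0.0056, adjusted p = 0.23 with an estimated correlation).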
